A study of Mus musculus with 5 samples.

How the data were processed

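RNA from small intestine of 5 mice was sequenced, 1 library per mouse, as total RNA with ribosomal RNA depletion per the labels' protocols. The labels do not state which stretch of the small intestine each library came from. The authors deposited 1 table of estimated counts for 19198 genes by symbol, with 1 column per mouse. The submitters' processing notes name Partek and the mm10 build, and the version, aligner, annotation, strand setting and counting rule are not given in the sources used here. Between 19.6% and 21.6% of the deposited values in a library were not whole (farther than 0.005 from a whole number), and they held 34.5% to 40.9% of the counts, so reads shared between genes had been divided among them. The lowest total of a gene over the 5 libraries was 10, so genes with fewer counts were absent from the table used. The estimated counts were rounded to whole numbers, and no scaling was applied before that. Every column belonged to a mouse of the series, and 0 rows named no gene.

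Mice were grouped by the genotype label, with 3 Cre-negative and 2 Cre-positive mice. Replicate numbers follow the order of the records and pair no mice. Library totals ran from 4681119 to 6618204 estimated counts. Counts of 10 or more in 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) were found in 5 of 5 libraries, and this list was too short for a list test.

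The main test was edgeR 4.0.16 under R 4.3.3: TMM factors, the filter filterByExpr with a minimum count of 10, robust quasi-likelihood fitting on genotype alone and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter left 14352 genes and removed 4846. It asks for enough counts in at least 2 libraries, the size of the smaller group, so the Cre-positive libraries alone can bring a gene past it. Standard errors of log2 fold changes were taken as the size of the fold change divided by the square root of the quasi-likelihood F, with edgeR's default prior count. Fold changes are Cre-positive over Cre-negative throughout. Chrm1 did not pass the filter, and its fold change came from the same fit without a filter. CPM values were scaled by TMM and are given as mean ± SD over mice. The biological coefficient of variation was 33.1%, with 3 residual degrees of freedom. Group differences of single values were tested with exact permutation tests over the 10 splits, two-sided, which cannot go below 0.1.

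Gene lists were fixed before the data were examined, 41 in all, for cell types of the intestine, region, immune programs, metabolism and RNA quality. Lists with at least 5 members among the genes tested entered limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 38 lists. The granulocyte and mast cell, blood and Y-linked lists had 3, 3 and 4 members and were not tested. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. Genes to name were set by a rule fixed before the data were examined. It takes the muscarinic receptor genes and Atoh1, and in each direction 12 genes past the threshold with a mean log2 CPM of at least 1 and groups that do not overlap. Predicted models, pseudogenes and variable segments were left out. Where too few genes passed, the smallest unadjusted p filled the places, which was the case for all 12 in each direction. It also takes 4 members of each list called and 2 members of the secretory and stem cell lists. Not every gene that the rule takes is reported here. Other genes named in the closing section were chosen after their values were seen.

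Coordinates came from GENCODE M21 on GRCm38, the assembly that mm10 denotes, and 18923 symbols (98.6%) matched it. Of 108 genes that the rule named, 107 had coordinates. Exons overlapped another gene on the same strand for 12 of them and on the opposite strand for 15, among them Chrm2, Clca4a, Ifi47, Tmem47, Tmem200a and Plagl1. Strand use in counting is not given in the sources used here, so reads of such pairs cannot be separated. For 33 named genes at least 1 library held a value that was not whole.

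The gene and list tests were tested on simulated data, with counts drawn for 14352 genes from the real means, spreads and library sizes. Of genes changed 2-fold, 0 of 96 were called, and of genes changed 4-fold, 45 of 98, while 13 unchanged genes were also called. Median recovered log2 fold changes were 0.95 and 2.00. Of simulated lists of 25 genes, 5 of 5 raised 1.5-fold were called and 0 of 33 unchanged ones, in simulated genes that vary independently of each other.

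Alternatives fixed before the data were examined were RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom, fitting without robust estimation, no filter, a stricter filter of 5 CPM in 2 libraries, adjusted p thresholds of 0.1 and of 0.05 with a log2 fold change of at least 1, and leaving out each mouse. A region score and a muscle score as covariates were added after seeing the data. A fit that leaves 1 Cre-positive mouse assumes that it varies like the others.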

Results

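The comparison asked what changed in the mouse small intestine when the M4 muscarinic acetylcholine receptor gene, Chrm4, was targeted in cells that express Math1. Math1 (gene symbol Atoh1) is the transcription factor that directs intestinal precursors into the secretory lineage, which holds goblet, Paneth and enteroendocrine cells. Cre*PR is a Cre recombinase fused to a progesterone receptor domain, and it becomes active when the mouse receives RU486, a synthetic progesterone receptor ligand. RNA was sequenced from small intestine after removal of ribosomal RNA, and the labels do not state the stretch sampled. The Cre-positive group held 2 mice with the Math1Cre*PR transgene and floxed Chrm4, and the Cre-negative group held 3 floxed littermates without the transgene. All 5 mice received RU486 by gavage at 10 mg/kg daily for 4 days, so the drug itself did not differ between the groups. The series held no Cre-positive mouse with unfloxed Chrm4. Effects of the activated Cre and of targeting Chrm4 therefore cannot be told apart. Each library came from a mouse with its own number in the labels. Estimated counts summed to 4681119, 5311648 and 5705921 in Cre-negative 1, 2 and 3 and to 5000613 and 6618204 in Cre-positive 1 and 2. Mitochondrially encoded genes took 20.8% ± 3.27 (SD, n = 3) of the counts in Cre-negative and 18.3% ± 0.704 (SD, n = 2) in Cre-positive libraries (exact permutation test, two-sided p = 0.5; the smallest p that 3 against 2 can give is 0.1). No pair of libraries agreed within sampling noise: the chi-square per degree of freedom ranged from 11.6, between Cre-negative 3 and Cre-positive 2, to 47.8, between Cre-negative 3 and Cre-positive 1.

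Chrm4 transcripts were scarce in both groups and no difference between the groups was detectable at this depth. Chrm4 (chromosome 2, 91927249 to 91928688, plus strand, GRCm38, 1 annotated exon block) had 4, 20 and 4 counts in Cre-negative 1, 2 and 3, or 0.959, 3.71 and 0.652 CPM (counts scaled to library size). It had 13 and 5 counts in Cre-positive 1 and 2, or 2.52 CPM (exact Poisson 95% interval 1.34 to 4.30) and 0.777 CPM (0.252 to 1.81). These intervals cover counting error only. The log2 fold change of Cre-positive over Cre-negative was -0.14 ± 0.91 (SE; edgeR adjusted p = 0.989), and it turned to 0.52 without Cre-positive 2 and to -1.15 without Cre-positive 1. Small intestine tissue also holds cells in which this Cre is not expressed, and the labels do not state which part of the gene is floxed, so these counts neither check nor contradict the genotype labels. Chrm2, the M2 receptor gene of smooth muscle, was the muscarinic receptor gene with the most counts, at 77.7 ± 25.4 CPM (SD, n = 3) in Cre-negative and 29.6 ± 7.63 CPM (SD, n = 2) in Cre-positive mice. Its log2 fold change was -1.39 ± 0.34 and it did not pass the test over all genes (edgeR adjusted p = 0.977). Chrm3, the M3 receptor gene, averaged 2.86 ± 1.56 and 2.52 ± 0.267 CPM. Chrm1, the M1 receptor gene, averaged 1.22 ± 0.461 and 1.20 ± 1.04 CPM, and Chrm5 was absent from the count table used. Atoh1 averaged 6.09 ± 2.37 CPM in Cre-negative mice and stood at 20.9 and 5.44 CPM in Cre-positive 1 and 2 (log2 fold change 1.09 ± 0.60; edgeR adjusted p = 0.977). Its log2 fold change was -0.15 without Cre-positive 1 and 1.79 without Cre-positive 2.

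**Figure D1:**
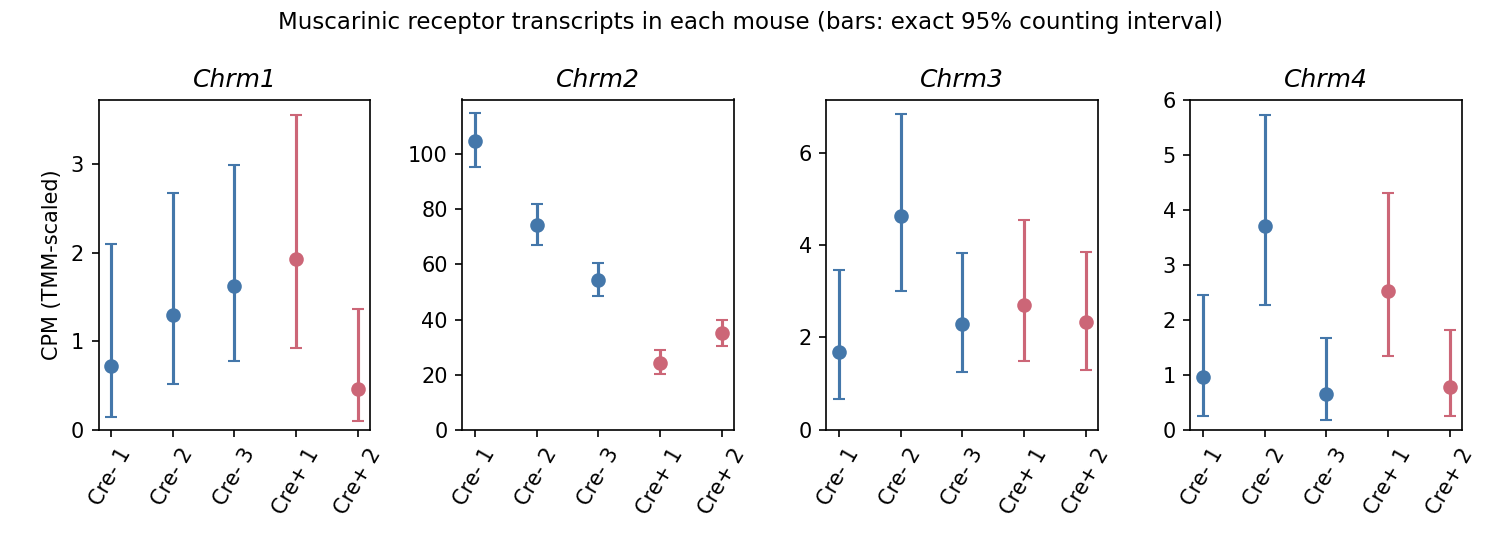
CPM of Chrm1, Chrm2, Chrm3 and Chrm4 in each of the 5 mice (linear axes starting at 0; blue, Cre-negative; red, Cre-positive; bars, exact Poisson 95% intervals of the counts). Chrm2 lay between 54.3 and 104.7 CPM in Cre-negative and at 24.2 and 35.0 CPM in Cre-positive mice, while the other receptors overlapped between the groups.

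No gene passed the test for a difference between Cre-positive and Cre-negative intestine. The named genes with the smallest unadjusted p were Ly6m, Fer1l6 and Nts on the higher side and Lenep, Ogn and Ifi205 on the lower side. Clca1, a protein that goblet cells secrete into mucus, averaged 63.2 ± 43.0 CPM (SD, n = 3) in Cre-negative and 631 ± 485 CPM (SD, n = 2) in Cre-positive mice. Muc2, the gel-forming mucin of intestinal mucus, averaged 495 ± 151 and 1553 ± 725 CPM. Ccl2, a chemokine that attracts monocytes, averaged 24.6 ± 10.97 CPM in Cre-negative and 4.14 ± 3.44 CPM in Cre-positive mice. Of 14352 genes tested with edgeR's quasi-likelihood test, 0 were called higher and 0 lower (lowest Benjamini-Hochberg adjusted p = 0.977). At an unadjusted p under 0.05 there were 230 higher and 255 lower genes, 485 in all, where chance would give 718. The groups did not overlap for 18.1% of genes tested, against 20% by chance. The DESeq2 Wald test called 12 genes higher and 7 lower, limma-voom called 0 and 0, and edgeR without Cre-positive 2 called 58 higher and 0 lower.

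The named genes that follow had CPM values that did not overlap between the groups and the smallest unadjusted p, and none passed edgeR's test over all genes (adjusted p = 0.977 for each). On the higher side, Clca1 had a log2 fold change of 3.32 ± 0.68, the goblet cell trefoil peptide Tff3 2.50 ± 0.56 and Muc2 1.65 ± 0.40. Without Cre-positive 1, Clca1 had 2.22 and Tff3 1.85, and without Cre-negative 3 they had 4.09 and 3.27. Without Cre-positive 2, Clca1 had 3.98. The cytotoxic protease gene Gzmb had a log2 fold change of 3.13 ± 0.61, the immunoglobulin light chain gene Iglc1 3.64 ± 0.73 and the nucleotide receptor gene P2ry4 3.55 ± 0.80. Without Cre-positive 1 these were 2.09, 2.16 and 2.32, and without Cre-positive 2 they were 3.77, 4.40 and 4.25. P2ry4 had 4.59 without Cre-negative 3. Nts, which encodes the hormone neurotensin, averaged 8.33 ± 1.45 and 23.0 ± 3.06 CPM, and Ly6m averaged 99.8 ± 10.5 and 231 ± 19.4 CPM. The interferon-inducible GTPase genes Ifi47 and Irgm1 had log2 fold changes of 1.14 ± 0.24 and 1.63 ± 0.35. Clca4a, an enterocyte gene, had 1.27 ± 0.27 and Fer1l6 1.77 ± 0.34. On the lower side, Ccl2 had a log2 fold change of -2.58 ± 0.66 and the related chemokine gene Ccl7 -2.25 ± 0.58. Without Cre-positive 1 these were -3.78 and -2.96, and Ccl2 had -1.85 without Cre-positive 2. Ogn, a matrix proteoglycan gene, averaged 82.3 ± 27.7 and 26.9 ± 2.44 CPM, and Olr1, a scavenger receptor gene for oxidized lipoprotein, averaged 22.4 ± 12.2 and 3.37 ± 1.25 CPM. Ifi205, of an interferon-inducible family, had a log2 fold change of -2.71 ± 0.56. The remaining lower genes were Dgkb at -1.78 ± 0.44, Tmem47 at -1.86 ± 0.47, Tmem200a at -1.75 ± 0.46, the imprinted transcription factor gene Plagl1 at -1.45 ± 0.39, the calcium channel gene Cacna1e at -1.07 ± 0.29 and Chrm2. Lenep had 14, 21 and 20 counts in the Cre-negative libraries and 0 in both Cre-positive libraries after rounding. Its only exon overlaps Flad1 on the same strand (chromosome 3, 89400988 to 89402793, minus strand), and the summed counts of Flad1 and Lenep were 50, 82 and 75 in Cre-negative and 61 and 70 in Cre-positive libraries. The deposited counts of Ifi205, Clca4a, Lenep, Ly6m and Muc2 were not whole in at least 1 library, so reads had been divided with other genes and their values are uncertain. The same limit applies to genes given below. Among others, H2-Aa, Rps20, Rps7, Rps23, Krt8, Clca4b, Abcb1b, Defa3, Gsta1, mt-Nd4l and mt-Nd2 were not whole in 5 libraries. Ccnb1, Pcna, Reg3g and Reg3b were not whole in 4. DESeq2 gave adjusted p = 0.00144 for Clca1, 0.00569 for Ifi205, 0.00606 for Ly6m, 0.0105 for Gzmb, Iglc1 and P2ry4, 0.0145 for Clca4a, 0.0163 for Tff3 and Olr1, 0.0203 for Fer1l6, 0.023 for Lenep, 0.033 for Ogn and 0.0447 for Ccl2 and Nts. It gave 0.0586 for Irgm1, 0.0656 for Muc2, 0.144 for Ifi47, 0.117 for Dgkb and 0.214 to 0.897 for Chrm2, Tmem47, Plagl1, Cacna1e, Ccl7 and Tmem200a. The lowest adjusted p of any gene with limma-voom was 0.978.

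Goblet cell genes rose as a list in Cre-positive intestine, with the lowest adjusted p of the lists tested. Of 24 members tested, 23 had a positive log2 fold change and the median was 1.16 (limma camera with a preset correlation, adjusted p = 2.77e-12; adjusted p = 0.606 with an estimated correlation). Over all genes 0 members passed the test, and 5 passed as higher when adjusted over the list alone. Zg16, a granule protein that binds bacterial cell walls, averaged 21.8 ± 20.7 CPM (SD, n = 3) in Cre-negative and 145 ± 46.1 CPM (SD, n = 2) in Cre-positive mice, beside Clca1, Tff3 and Muc2. Its log2 fold change of 2.72 became 3.92 without Cre-negative 3. The list score, the mean log2 CPM of the members, was 4.20 ± 0.31 in Cre-negative mice and stood at 5.87 and 4.86 in Cre-positive 1 and 2 (exact permutation test, two-sided p = 0.1, the smallest possible). The list stayed past the preset test without each mouse in turn, with a highest adjusted p of 3.44e-05 without Cre-positive 1. Paneth cell genes fell as a list, with 22 of 24 members negative and a median of -0.43 (adjusted p = 0.0418; adjusted p = 0.717 with an estimated correlation). Their call was lost without Cre-negative 2 (0.843), Cre-negative 3 (0.287) or Cre-positive 2 (0.344). Among them the crypt defensin gene Defa3 averaged 11.9 ± 6.04 and 7.06 ± 0.130 CPM, the lipase gene Pnliprp2 29.1 ± 13.3 and 14.1 ± 1.60 CPM, Habp2 6.31 ± 3.26 and 2.27 ± 0.350 CPM, and Clps, the colipase gene, 5.25 ± 1.07 and 2.66 ± 0.200 CPM. Enteroendocrine genes rose as a list, with 7 of 11 members positive and a median of 0.64 (adjusted p = 0.0382; adjusted p = 0.606 with an estimated correlation). That call was lost without Cre-negative 1 (0.168), Cre-negative 3 (0.0832) or Cre-positive 1 (0.849) and with the region (0.15) or muscle (0.273) score as a covariate, and Nts alone passed when adjusted over the list alone. Only 11 of the 30 fixed enteroendocrine members passed the expression filter, which the Cre-positive libraries alone can satisfy. The secretin gene Sct passed in this way, with 6 counts in each Cre-negative library and 31 and 18 in Cre-positive 1 and 2. The share of positive members may therefore reflect this selection. Sct averaged 1.18 ± 0.237 and 4.40 ± 2.26 CPM, the proglucagon gene Gcg 5.08 ± 3.65 and 16.4 ± 15.1 CPM, and the prohormone convertase gene Pcsk1 9.50 ± 4.50 and 15.0 ± 8.40 CPM. Without Cre-positive 1 the log2 fold change went from 1.89 to 1.29 for Sct, from 1.66 to 0.19 for Gcg and from 0.64 to -0.06 for Pcsk1, and Gcg had 2.43 without Cre-positive 2 and 2.49 without Cre-negative 3. Tuft cell genes did not pass (adjusted p = 0.137, 20 members, median -0.25). Their members with the smallest p were Ptprc, the pan-leukocyte gene CD45, at 14.9 to 159 CPM in Cre-positive mice, and Sh2d6 at a log2 fold change of -0.97 ± 0.48. The log2 fold change of Ptprc went from 2.33 to -0.17 without Cre-positive 1 and to 3.25 without Cre-positive 2. Stem cell genes did not pass either (adjusted p = 0.366, 19 members), and their median of -0.04 lay below 0 while their mean was 0.13. Lgr5, the marker of crypt base stem cells, averaged 3.90 ± 1.29 and 10.3 ± 4.39 CPM, and Aqp4, a water channel gene, 14.4 ± 10.3 and 34.9 ± 26.2 CPM. The log2 fold change of Aqp4 went from 1.26 to 0.19 without Cre-positive 1, 1.90 without Cre-positive 2 and 2.02 without Cre-negative 3. Secretory lineage regulators did not pass (adjusted p = 0.636, 16 members, median -0.01, mean 0.08).

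**Figure D2:**
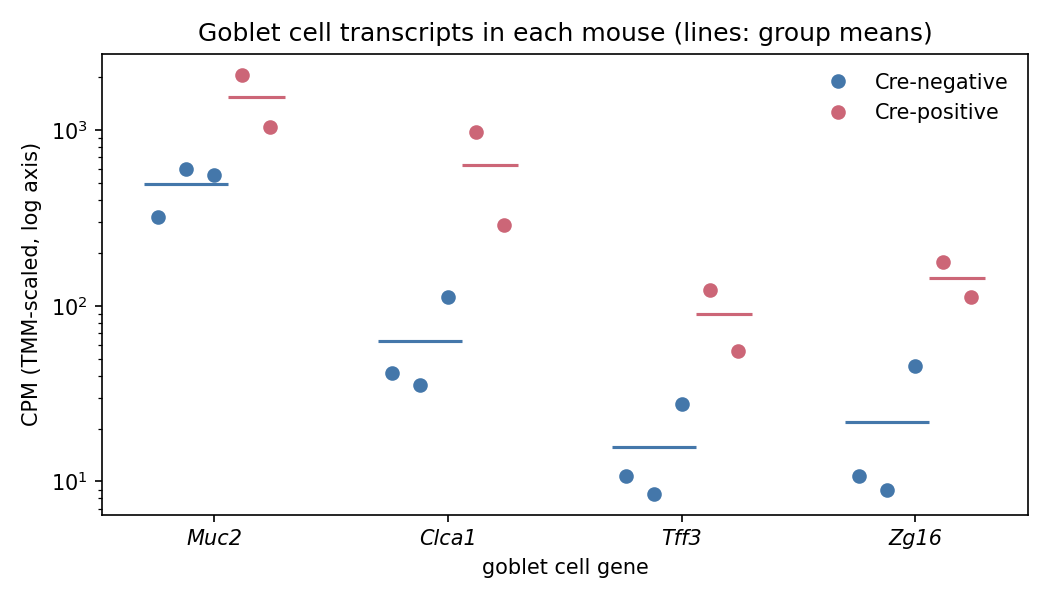
CPM of the goblet cell genes Muc2, Clca1, Tff3 and Zg16 in each of the 5 mice on a log axis (blue, 3 Cre-negative; red, 2 Cre-positive; lines, group means). Both Cre-positive mice lay above all Cre-negative mice for each gene, with Muc2 at 1040 and 2065 CPM against at most 604 CPM. The rule that named Muc2, Clca1 and Tff3 asks for groups that do not overlap, so their separation follows from that choice. Of the 24 goblet list members tested, 13 separated as higher and 1 as lower.

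Lymphocyte and interferon lists rose in Cre-positive intestine under the preset correlation, and 3 of these calls were lost without Cre-positive 1. B and plasma cell genes had 12 of 13 members positive and a median log2 fold change of 2.91 (camera adjusted p = 8.59e-06; adjusted p = 0.606 with an estimated correlation), with 0 members called over all genes and 7 adjusted over the list alone. These 13 were what the expression filter left of 36 fixed members, and the Cre-positive libraries alone can satisfy that filter. Iglc1 passed in this way, with 3, 4 and 8 counts in Cre-negative 1, 2 and 3 and 103 and 27 in Cre-positive 1 and 2. The share of positive B and plasma cell members may therefore reflect this selection. The call was lost without Cre-positive 1 (adjusted p = 0.0888). Ighm, the IgM heavy chain gene, stood at 113 CPM in Cre-positive 1 and 1.40 CPM in Cre-positive 2, against 1.77 ± 0.727 CPM (SD, n = 3) in Cre-negative mice. Pou2af1, a coactivator of immunoglobulin genes, stood at 52.8 and 2.02 CPM against 1.17 ± 0.257 CPM, and Prdm1, the plasma cell regulator, at 52.6 and 26.0 CPM against 15.8 ± 3.97 CPM. Without Cre-positive 1 the log2 fold change went from 5.02 to -0.29 for Ighm and from 4.54 to 0.83 for Pou2af1, and without Cre-positive 2 they had 6.04 and 5.53. T cell and innate lymphoid genes had 6 of 6 members positive and a median of 1.46 (adjusted p = 0.000306; adjusted p = 0.606 with an estimated correlation), and the call stayed without each mouse in turn. Only 6 of this list's 38 fixed members passed the expression filter. The Cre-positive libraries alone can satisfy that filter, so the share of positive members may reflect this selection. In this list Gzmb alone passed when adjusted over the list alone, while the co-receptor gene Cd8a averaged 1.72 ± 0.532 and 6.06 ± 4.84 CPM, Tcrg-C1 0.489 ± 0.847 and 3.57 ± 1.53 CPM and the integrin gene Itgae 1.82 ± 0.837 and 4.14 ± 3.44 CPM. Their size rested on single mice: without Cre-positive 1 the log2 fold change went from 1.79 to 0.65 for Cd8a and from 1.13 to -0.08 for Itgae, and without Cre-positive 2 they had 2.49 and 1.85. Tcrg-C1 had 0, 0 and 9 counts in Cre-negative 1, 2 and 3, so without Cre-negative 3 its fold change has no finite estimate. Interferon response genes had 27 of 37 members positive and a median of 0.36 (adjusted p = 0.000562; adjusted p = 0.606 with an estimated correlation), and the call was lost without Cre-positive 1 (0.158). Beside Irgm1, the interferon-inducible GTPase genes Iigp1 and Gbp7 had log2 fold changes of 1.56 ± 0.55 and 0.75 ± 0.27, and Iigp1 had 0.42 without Cre-positive 1 and 2.23 without Cre-positive 2. MHC class II presentation genes had 9 of 11 members positive and a median of 0.39 (adjusted p = 0.00125; adjusted p = 0.606 with an estimated correlation). The call stayed without each mouse in turn and was lost with the muscle score as a covariate (0.0614). Ciita, the class II transactivator gene, averaged 31.5 ± 11.2 and 63.8 ± 19.0 CPM, H2-Aa 493 ± 214 and 921 ± 74.7 CPM, H2-Eb1 101 ± 21.5 and 146 ± 8.57 CPM, and H2-Ab1 190 ± 77.4 and 273 ± 37.4 CPM. Peyer's patch epithelium genes had 9 of 11 members positive and a median of 0.58 (adjusted p = 0.00589; adjusted p = 0.606 with an estimated correlation). That call was lost without Cre-negative 3 (0.131) or Cre-positive 1 (0.857) and with the region score as a covariate (0.331). Ubd stood at 98.9 and 9.17 CPM in Cre-positive 1 and 2, against 0.719, 1.30 and 10.8 CPM in Cre-negative 1, 2 and 3. Marcksl1 stood at 82.8 and 34.5 CPM against 26.6, 35.2 and 16.5 CPM, and Ctsh at 27.5 and 14.6 CPM against 15.1, 10.7 and 14.0 CPM. For each of these genes Cre-positive 2 lay below the highest Cre-negative mouse. Serpinb1a averaged 339 ± 25.1 CPM in Cre-negative and 505 ± 36.3 CPM in Cre-positive mice. Without Cre-positive 1 the log2 fold change went from 3.59 to 1.08 for Ubd and from 1.17 to 0.44 for Marcksl1, and Ubd had 4.49 without Cre-positive 2 and 5.72 without Cre-negative 3. Inflammatory cytokine genes fell as a list, with 13 of 15 members negative and a median of -0.70 (adjusted p = 0.00343; adjusted p = 0.606 with an estimated correlation). The call was lost without Cre-positive 2 (0.665) and with the muscle score as a covariate (0.124), and adjusted over the list alone 2 members passed as lower and 1 as higher. Il6 averaged 18.4 ± 10.1 and 4.90 ± 2.10 CPM, and Ptgs2, the inducible cyclooxygenase gene, 35.8 ± 18.2 and 10.8 ± 6.66 CPM, beside Ccl2 and Ccl7. Ptgs2 went from a log2 fold change of -1.74 to -2.51 without Cre-positive 1. Macrophage and dendritic cell genes (adjusted p = 0.254, 18 members, median 0.26), type 2 immune response genes (0.213, 10 members, median 0.04, with 1 higher when adjusted over the list alone) and epithelial antimicrobial genes (0.433, 23 members, median -0.08) did not pass.

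Smooth muscle genes fell as a list, with 26 of 26 members negative and a median log2 fold change of -0.83 (camera adjusted p = 8.59e-06; adjusted p = 0.657 with an estimated correlation). The call stayed without each mouse in turn, with a highest adjusted p of 0.0145, and was lost with the list's own score as the muscle covariate (0.964). The actin-binding protein gene Cald1 averaged 327 ± 155 CPM (SD, n = 3) in Cre-negative and 146 ± 5.72 CPM (SD, n = 2) in Cre-positive mice, Synpo2 184 ± 105 and 75.9 ± 2.31 CPM, the tropomyosin gene Tpm2 26.4 ± 14.0 and 10.9 ± 3.32 CPM, and Pdlim3 26.3 ± 13.0 and 12.1 ± 1.30 CPM. The list scores overlapped, at 6.69, 5.66 and 5.16 in Cre-negative 1, 2 and 3 and 5.16 and 5.24 in Cre-positive 1 and 2. The estimated correlation between the smooth muscle members was 0.87, so their shared sign is far from independent evidence. Enteric neuron and glia genes fell with 10 of 12 members negative and a median of -0.45 (adjusted p = 0.0345; adjusted p = 0.606 with an estimated correlation), and the call was lost without Cre-negative 1 (0.507), Cre-negative 2 (0.178) or Cre-positive 2 (0.0828) and with the muscle score as a covariate (0.743). Snap25, of the synaptic vesicle fusion machinery, averaged 5.22 ± 0.719 and 1.96 ± 0.307 CPM, and Elavl4, Stmn2 and Slc5a7, the neuronal choline transporter gene, had log2 fold changes of -1.17 ± 0.62, -0.89 ± 0.57 and -0.97 ± 0.65. Slc5a7 had -0.37 without Cre-positive 1 and -2.01 without Cre-positive 2. Muscarinic and cholinergic genes fell with 13 of 16 members negative and a median of -0.26 (adjusted p = 0.0349; adjusted p = 0.606 with an estimated correlation). Their call was lost without Cre-negative 1 (0.0517), Cre-negative 2 (0.0813) or Cre-positive 2 (0.379), with the strict filter (0.102) and with the muscle score as a covariate (0.186). Beside Chrm2, the nicotinic receptor gene Chrna3 had a log2 fold change of -1.52 ± 0.58, the adenylyl cyclase gene Adcy5 -0.95 ± 0.39 and the G protein gene Gnao1 -0.68 ± 0.41. Interstitial cell of Cajal genes (adjusted p = 0.0508, 11 members, median -0.47), fibroblast and matrix genes (0.0817, 25 members, median -0.43), endothelial and lymphatic genes (0.205, 13 members, median -0.47), adipose genes (0.238, 11 members, median -0.27) and immediate early genes (0.197, 26 members, median -0.44) did not pass.

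Cell cycle genes rose as a list, with 32 of 32 members positive and a median log2 fold change of 0.45 (camera adjusted p = 1.21e-05; adjusted p = 0.667 with an estimated correlation), and the call was lost without Cre-negative 1 (0.166) or Cre-positive 1 (0.615) and turned to the lower side with the muscle score as a covariate (0.47). The list scores overlapped, at 2.24, 3.23 and 3.85 in Cre-negative 1, 2 and 3 and 4.16 and 3.20 in Cre-positive 1 and 2 (exact permutation test, two-sided p = 0.5). The estimated correlation between members was 0.85, so their shared sign is far from independent evidence. Top2a, the topoisomerase of dividing cells, stood at 24.4, 44.3 and 101 CPM in Cre-negative 1, 2 and 3 and 167 and 59.5 CPM in Cre-positive 1 and 2. Ccnb1, Hmmr and Pcna had log2 fold changes of 1.14 ± 0.74, 0.85 ± 0.54 and 0.51 ± 0.31. Without Cre-positive 1 Ccnb1 had 0.36 and Top2a 0.10, without Cre-negative 3 Ccnb1 had 1.94, Top2a 1.76 and Hmmr 1.48, and Top2a had 1.59 without Cre-positive 2. Replication-dependent histone genes had 15 of 15 members positive and a median of 0.58 (adjusted p = 0.0015; adjusted p = 0.606 with an estimated correlation), lost without Cre-positive 1 (0.634) and with the muscle covariate (0.0996). Hist1h4d had a log2 fold change of 0.91 ± 0.33, Hist1h3b 0.75 ± 0.51, Hist1h3a 0.63 ± 0.40 and Hist1h1d 0.61 ± 0.42. Counts of Hist1h3a and Hist1h3b were not whole in 5 libraries and those of Hist1h4d and Hist1h1d in 4. Reads of each had therefore been divided with other genes. Without Cre-positive 1 Hist1h3b had 0.03, Hist1h3a -0.01 and Hist1h1d -0.09. Cytosolic ribosomal protein genes had 33 of 40 members positive and a median of 0.25 (adjusted p = 8.04e-05; adjusted p = 0.606 with an estimated correlation), lost without Cre-positive 1 (0.337) and with the muscle covariate (0.0852). Rps20 averaged 32.6 ± 4.50 CPM (SD, n = 3) and 64.9 ± 15.5 CPM (SD, n = 2), and Rps7, Rpl32 and Rps23 had log2 fold changes of 0.88 ± 0.34, 0.87 ± 0.36 and 0.82 ± 0.42, with Rpl32 at 0.20 without Cre-positive 1. Unfolded protein response genes had 25 of 36 members positive and a median of 0.26 (adjusted p = 0.0042; adjusted p = 0.606 with an estimated correlation), lost without Cre-positive 1 (0.343) and with the region (0.0523) or muscle (0.0996) score as a covariate. Edem1, of endoplasmic reticulum degradation, averaged 201 ± 5.09 and 281 ± 4.74 CPM, the chaperone gene Hspa5 137 ± 22.0 and 234 ± 94.1 CPM, Manf 69.6 ± 17.1 and 117 ± 25.2 CPM, and Sdf2l1 0.635 ± 0.550 and 4.07 ± 2.46 CPM. Sdf2l1 went from a log2 fold change of 2.54 to 1.79 without Cre-positive 1. Mitochondrially encoded genes fell with 13 of 13 members negative and a median of -0.31 (adjusted p = 0.011; adjusted p = 0.698 with an estimated correlation), lost without Cre-negative 1 (0.368) or Cre-positive 1 (0.156) and with the muscle score as a covariate (0.964). The estimated correlation between the mitochondrially encoded members was 0.91, so their shared sign is also far from independent evidence. Among them mt-Nd4l, mt-Nd2, mt-Nd1 and mt-Atp8 had log2 fold changes of -0.56 ± 0.25, -0.54 ± 0.33, -0.49 ± 0.35 and -0.38 ± 0.28. Nuclear oxidative phosphorylation genes (adjusted p = 0.625, 30 members, median 0.01) and clock genes (0.388, 18 members, median -0.25) did not pass.

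Among absorptive and barrier lists, proximal enterocyte genes fell with 25 of 32 members negative and a median log2 fold change of -0.33 (camera adjusted p = 0.0418; adjusted p = 0.764 with an estimated correlation). This rested on Cre-positive 1: without it the list was past the threshold in the higher direction (0.0011), and the call was also lost without Cre-negative 1 (0.112) or Cre-negative 3 (0.702) and with the muscle covariate (0.0614). With the region covariate, which holds this list's own score, it turned to the higher side (0.0768). The lipoprotein receptor gene Scarb1 had a log2 fold change of -1.61 ± 0.75, the iron reductase gene Cybrd1 -0.98 ± 0.65, Khk, which phosphorylates fructose, -0.71 ± 0.72 and Gsta1 -0.44 ± 0.31. Cybrd1 had -0.06 without Cre-negative 1, and Khk had 0.05 without Cre-positive 1 and -2.25 without Cre-positive 2. Drug and retinoid metabolism genes fell with 27 of 36 members negative and a median of -0.30 (adjusted p = 0.0423; adjusted p = 0.717 with an estimated correlation). The call was lost without Cre-negative 1 (0.166) or Cre-negative 3 (0.342) and with the muscle covariate (0.0996), and it turned to the higher side without Cre-positive 1 (0.357) and with the region covariate (0.361). Abcb1b, an efflux pump gene, had -2.05 ± 0.78, Gstm1 -1.31 ± 0.52, Cyp3a44 -1.72 ± 0.98 and Gsta4 -0.72 ± 0.43. Without Cre-positive 2 Gstm1 had -1.94 and Cyp3a44 -2.45. Distal small intestine genes rose with 11 of 18 members positive and a median of 0.24 (adjusted p = 0.0349; adjusted p = 0.606 with an estimated correlation). That call was lost without Cre-negative 3 (0.3) or Cre-positive 2 (0.874) and with the region score as a covariate (0.126), and Nts alone passed when adjusted over the list alone. The region score holds the distal list's own score, so the loss with that covariate is no separate evidence. Nts is also a member of the enteroendocrine list. The protease gene Mep1b averaged 555 ± 93.9 CPM (SD, n = 3) and 801 ± 12.3 CPM (SD, n = 2), the bile acid exporter gene Slc51b 77.1 ± 46.0 and 180 ± 126 CPM, and Clca4b 2399 ± 169 and 3204 ± 359 CPM. The log2 fold change of Slc51b went from 1.22 to 0.27 without Cre-positive 1, 1.84 without Cre-positive 2 and 1.81 without Cre-negative 2. Tight junction and barrier genes rose with 21 of 29 members positive and a median of 0.14 (adjusted p = 0.0174; adjusted p = 0.606 with an estimated correlation), lost without Cre-negative 1 (0.0666) or Cre-positive 2 (0.318) and with the muscle covariate (0.106). The keratin gene Krt8 averaged 326 ± 38.7 and 483 ± 54.8 CPM, and the claudin genes Cldn8, Cldn23 and Cldn12 had log2 fold changes of 1.77 ± 0.85, 0.62 ± 0.31 and 0.49 ± 0.26. Cldn8 stood at 19.0 and 1.87 CPM in Cre-positive 1 and 2 against 3.06 CPM in the Cre-negative mean, and its log2 fold change was -0.65 without Cre-positive 1 and 2.69 without Cre-positive 2. The exocrine pancreas list rose with 5 of 6 members positive and a median of 0.51 (adjusted p = 0.0339; adjusted p = 0.606 with an estimated correlation), lost without Cre-negative 1 (0.0666) or Cre-positive 2 (0.434) and with the muscle covariate (0.0996). Of the 32 fixed members of this list, 6 passed the expression filter. Its leading members were Zg16 and Klk1, which the goblet cell list also held, and Klk1, a kallikrein protease gene, averaged 1.35 ± 0.527 and 5.25 ± 4.34 CPM. Klk1 went from a log2 fold change of 1.93 to 0.72 without Cre-positive 1 and 2.65 without Cre-positive 2. The trypsin inhibitor gene Spink1 had a log2 fold change of 0.71 ± 0.40 and the secretory cell transcription factor gene Bhlha15 0.30 ± 0.56, and 1 member passed when adjusted over the list alone. Fat oxidation and ketogenesis genes (adjusted p = 0.0514, 25 members, median -0.21), cholesterol synthesis genes (0.266, 27 members, median 0.08) and ion and water transport genes (0.91, 28 members, median -0.16) did not pass.

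**Figure D3:**
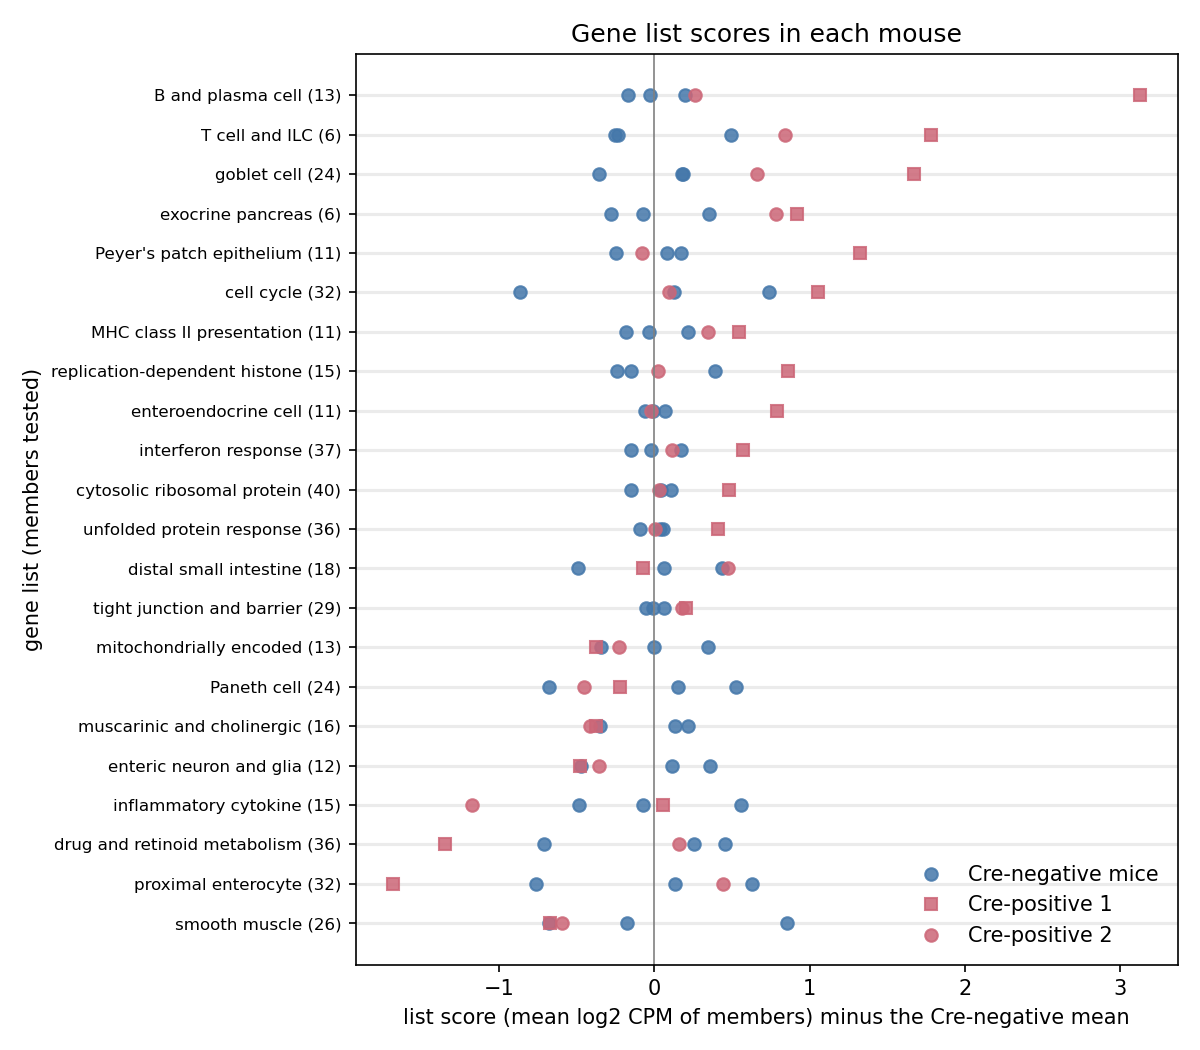
Score of each of the 22 gene lists past the preset-correlation test in each of the 5 mice, as mean log2 CPM of the members minus the mean of the 3 Cre-negative mice (blue circles, Cre-negative; red squares, Cre-positive 1; red circles, Cre-positive 2; members tested in parentheses). The B and plasma cell score of Cre-positive 1 was 5.88 against 2.75 in the Cre-negative mean, and 0 of the 22 lists passed with an estimated correlation.

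In all, 14 of 38 lists were called higher and 8 lower under the preset correlation of 0.01, and 16 were not called. With an estimated correlation 0 were called, and with fry 0 were called in a given direction and 0 in either direction. Exact permutation tests of the list scores gave p = 0.1 for the goblet, B and plasma cell, T cell and barrier lists. They gave 0.2 for the MHC class II, exocrine pancreas and cholinergic lists. The scores of the other called lists overlapped between the groups and gave 0.3 to 0.6. Of the lists called, members called over all genes numbered 0 in each, and the counts adjusted over the list alone were 0 except where given. The region score, the proximal enterocyte minus the distal small intestine list score, overlapped between the groups and was 0.26, -0.26 and 1.69 in Cre-negative 1, 2 and 3 and -1.04 and 0.53 in Cre-positive 1 and 2.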

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

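No paired analysis was possible because the labels give the groups no shared replicate numbers. The covariate fits were chosen after seeing the data, and the cause of each change below was not tested unless fewer mice explain it by construction. The counts of 0 higher and 0 lower genes held under RLE, upper-quartile and total-count scaling, limma-voom, non-robust fitting, both filters, both thresholds and both covariates. DESeq2 called 12 higher and 7 lower, with 1 adjusted p left as NA. Leaving out each mouse gave 0 to 58 higher, with 58 only without Cre-positive 2, and 0 lower genes in each fit. Lists called higher went from 14 to 0 with an estimated correlation, 0 with fry, 9 with the muscle covariate and 8 to 16 on leaving out a mouse. Lists called lower went from 8 to 0, 0, 1 and 3 to 11 in the same fits. Under the muscle covariate 14 of the 22 called lists lost their call in the same direction: smooth muscle (0.964), cytosolic ribosomal protein (0.0852), MHC class II (0.0614), histone (0.0996), inflammatory cytokine (0.124), unfolded protein response (0.0996), mitochondrially encoded (0.964), barrier (0.106), exocrine pancreas (0.0996), enteric neuron and glia (0.743), muscarinic and cholinergic (0.186), enteroendocrine (0.273), proximal enterocyte (0.0614) and drug and retinoid metabolism (0.0996). Under the region covariate, which holds the distal list's own score, 4 did: unfolded protein response (0.0523), Peyer's patch epithelium (0.331), distal small intestine (0.126) and enteroendocrine (0.15). The strict filter ended the muscarinic and cholinergic call (0.102) and left the T cell and ILC, exocrine pancreas, enteric neuron and glia and enteroendocrine lists too short to test. It also brought the fat oxidation (0.0417) and adipose (0.0417) lists past the threshold in the lower direction. RLE (0.0443) and total-count (0.0392) scaling did so for the interstitial cell of Cajal list and changed no other list call. With the muscle covariate the cell cycle list turned lower (adjusted p = 0.47), and the fibroblast (0.000428) and immediate early (0.0065) lists turned higher. With the region covariate the proximal enterocyte (0.0768) and drug and retinoid metabolism (0.361) lists turned higher. That covariate also brought 6 lists past the threshold. The tuft cell (0.00193), fibroblast (1.46e-05), endothelial (0.00115), interstitial cell of Cajal (0.0036) and immediate early (0.00584) lists were lower, and oxidative phosphorylation (0.0359) was higher. The muscle covariate brought the macrophage and dendritic cell list past it as higher (0.000852). On leaving out each mouse the adjusted p ranged from 2.91e-08 to 0.702 for proximal enterocyte genes, from 9.61e-05 to 0.357 for drug and retinoid genes and from 0.000215 to 0.754 for macrophage and dendritic cell genes. Proximal enterocyte (0.0011), drug and retinoid (0.357) and macrophage (0.0218) lists turned direction without Cre-positive 1. Chrm4 ranged from -1.15 to 0.52 in log2 fold change and Chrm3 from -0.42 to 0.33, and Chrm1 was 0.67 in the 1 such fit that kept it. Ranges that crossed 0 were also seen for Atoh1 (-0.15 to 1.79), Ighm (-0.29 to 6.04), Itgae (-0.083 to 1.85), Hist1h3a (-0.0094 to 1.14), Hist1h1d (-0.091 to 1.14), Cldn8 (-0.65 to 2.69), Pcsk1 (-0.062 to 1.15), Khk (-2.25 to 0.051) and Ptprc (-0.17 to 3.25). Bhlha15 was -0.037 with the region covariate and Cybrd1 0.17 with the muscle covariate. Depth limits Chrm1, Chrm3 and Chrm4 to 3 to 25 counts per library.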

Other observations

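Apart from leaving out Cre-positive 1, the tests in this part were chosen after the values were seen, and so were the genes beyond the naming rule. Cre-positive 1 differed from the other 4 libraries in genes of intestinal position and lymphoid follicles. Gata4, a transcription factor of the proximal intestine, stood at 0.387 CPM in it and between 19.8 and 47.4 CPM in the others. Lct, the lactase gene, stood at 3.48 CPM against 15.8 to 881 CPM, and Fabp1, an enterocyte fatty acid carrier gene, at 0 counts (an upper limit of 3 counts) against 6.86 to 102 CPM. Hoxb9, a posterior patterning gene, stood at 24.0 CPM in Cre-positive 1 and at most 1.11 CPM in the others, and the ileal bile acid transporter gene Slc10a2 at 810 CPM against 6.52 to 376 CPM. Fabp6, another ileal bile acid gene, did not set it apart, at 47.6 CPM against 47.7, 61.3 and 0.652 CPM in Cre-negative 1, 2 and 3 and 6.37 CPM in Cre-positive 2. The B cell genes Ms4a1 and Cr2 stood at 42.8 and 21.3 CPM against at most 2.41 and 1.96 CPM. The amino acid transporter gene Slc6a14 reached 180 CPM against at most 2.16 CPM.

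Several genes varied widely within a group. Pla2g4c, a phospholipase gene, stood at 3166 and 3458 CPM in Cre-negative 1 and 2, 18.2 CPM in Cre-negative 3, and 105 and 142 CPM in Cre-positive 1 and 2. The antimicrobial lectin gene Reg3g ran from 54.2 to 3474 CPM among Cre-negative mice and stood at 6076 and 1228 CPM in Cre-positive mice, and Reg3b ran from 62.5 to 2067 CPM and stood at 7823 and 1114 CPM.

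Higher goblet cell genes in Cre-positive mice may come from sampling a more distal stretch, from a smaller share of muscle, from Cre-positive 1 alone or from the genotype. The goblet list kept its preset-correlation call with the region (camera adjusted p = 1.52e-07) and muscle (1.34e-08) covariates and without Cre-positive 1. Its unadjusted camera p was under 0.05 in 6 of the 9 other groupings of the libraries. The lowest, 3.50e-11, set Cre-negative 1 and 3 against the rest. That grouping keeps both Cre-positive mice together, so it carries part of the same difference. With the Cre-positive mice in different groups the lowest was 4.00e-06, for Cre-negative 2 and Cre-positive 1 against the rest. The list did not pass with an estimated correlation (camera adjusted p = 0.606), so a kept call excludes none of these explanations. Between mice each stays open: with the region score in the model the genotype coefficient was 1.01 log2 units (95% interval -1.35 to 3.37), the goblet minus barrier score differed by 0.98 (SE 0.42, 95% interval -0.35 to 2.31), and Cre-positive 2 alone lay 0.66 above the Cre-negative mean (Cre-negative SD 0.31). An earlier reading rule, a gap of over 2 Cre-negative SDs (SD 0.27) with no overlap, would have counted the barrier difference against muscle, and it was replaced after the values were seen because 3 and 2 mice are too few for it. The goblet score difference was 1.17 against at most 0.93 in size in the other groupings and 22 lists were called against at most 21, so the real grouping was the 1 with values as large, and 10 splits are too few for a share under 0.05.

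Higher B cell and Peyer's patch genes in Cre-positive mice may come from follicle tissue in the Cre-positive 1 sample or from a genotype effect present in 1 of 2 mice, and neither was decided. The Peyer's patch epithelium score of Cre-positive 1 lay 1.15 log2 units above the highest of the other 4 libraries. Its B and plasma cell score lay 2.87 above the highest of the others, while Cre-positive 2 lay 0.26 above the Cre-negative mean. These scores are the pattern itself, so they place it in 1 library and do not show its source.

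Lower Chrm2 in Cre-positive mice may follow a smaller share of smooth muscle, and the libraries cannot decide this. Chrm2 minus the smooth muscle score differed by -0.72 log2 units between the groups (SE 0.29, 95% interval -1.66 to 0.22). With the muscle score as a covariate its log2 fold change was -0.96 ± 0.30 (edgeR adjusted p = 0.9999), and 0 of 26 smooth muscle genes had a lower fold change than Chrm2. The earlier 2-SD rule (Cre-negative SD 0.33) would have counted this against the muscle explanation and was replaced here too. A genotype effect on Chrm2 stays open.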
